A study of Mus musculus with 31 samples.

How the data were processed

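The data are bulk RNA-seq of the thalamus of 31 adult mice, at postnatal day 90 per the series design text. The mothers had either been reared in social isolation (SIR) or were controls. Per the labels' protocols, RNA was taken with the Qiagen AllPrep kit and polyadenylated RNA was made into libraries with Illumina's stranded mRNA ligation kit. Housing and sex were taken from the labels, which gave 7 SIR male, 8 SIR female, 8 control male and 8 control female libraries. The labels give neither litters nor batches, so the p-values measure the spread between these animals, and animals of one litter were counted as separate. The library numbers of the SIR animals all lie below those of the controls, so any difference in handling between number ranges cannot be told apart from housing.

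Per the submitters' processing notes, reads were inspected with FastQC, quantified with kallisto and referred to the build GRCm39, with versions not given in the sources used here. The deposited tables hold, per the file headers, an estimated count, a TPM value and an effective length for each of 105878 transcripts in each library. The estimated count is kallisto's share of the reads per transcript and need not be whole, per the file headers, and the authors did not normalize it as far as the values show. The TPM values deposited by the authors are scaled by effective length to the same total in each library, per the file headers. The effective length is another deposited value, given per transcript and library, per the file headers. Whether kallisto used the strand of the reads is not given in the sources used here, so values of overlapping and antisense genes are uncertain.

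Transcripts were matched to genes by identifier in GENCODE release M21, an annotation of the older build GRCm38. It was used for gene names, chromosomes and transcript sequences, and no coordinates are given because the builds differ. Of the transcripts, 104949 (99.12%) matched and gave 25497 genes. The other 929 transcripts, which took 0.69% to 0.76% of the counts of a library, were left out. No Xist transcript matched, so Xist was not analysed here. Estimated counts were summed per gene and rounded to whole numbers. Library totals ran from 13 to 25.74 M (mega) counts, with a median of 23.28 M. Each pair of libraries of one group differed by more than sampling noise, so each library was counted as 1 sample.

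Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups (14886 genes), scaled by TMM, and fitted with a mean for each of the 4 groups by the robust quasi-likelihood method. All 31 libraries shared 1 estimate of the spread (common biological coefficient of variation 0.13). The comparisons were SIR minus control as the mean of both sexes, within males and within females, the difference between the male and the female effect (the interaction), and males minus females. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Levels are counts-per-million (CPM) on TMM-scaled totals, given as mean ± SD, and log2 fold changes are given ± SE. Beside a within-group test, the number of libraries beyond the median of the other group is given.

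For the set tests, 38 gene lists covering cell types, neighbouring brain regions and pathways were tested with camera from limma 3.58.1 on voom values, with the preset inter-gene correlation of 0.01 and a minimum of 5 measured members. P-values were adjusted over the lists. Camera with an estimated inter-gene correlation and fry were run beside it. Fry tests whether the genes of a list move one way on balance and does not compare the list with other genes. List medians are medians of the edgeR log2 fold changes, except where the voom scale is named. A list score of a library is the mean over the members of log2 CPM centred per gene, with a prior count of 2.

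The design, the lists, the tests and most alternative settings were fixed before the data were examined. So was the rule for named genes: by smallest p, 12 genes per direction for the comparison over both sexes and 6 per direction for the others, plus list members that passed in any comparison and up to 4 members of each list. Gene models without a proper symbol were counted but not named, and some genes that the rule selected are not reported here. Alternatives fixed with them were other scaling factors (RLE and upper quartile), no filter and a filter of 1 CPM in 15 libraries, DESeq2 1.42.0, limma-voom with sample weights, transcript length offsets, limma-trend on log2(TPM + 1), an additive model, 2 surrogate variables from sva 3.50.0, and a principal component of the region marker scores. Others were a fit on the libraries compared alone, the libraries whose numbers lie apart from the rest left out, a threshold of 0.1, fitting without robust estimation, and each library left out in turn. Alternatives added after the data were seen were leaving out the 2 shallowest libraries, removing trends with transcript length or GC content within each library, thinning to the total of the shallowest library, 3 region components, these components without the library labelled SIR female 5, and the comparison of the sexes in SIR offspring without that library.

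The gene test was tested on simulated counts of 14807 genes drawn from the real means and library sizes. For the comparison over both sexes it recovered 18% of genes changed 1.1-fold, 58% at 1.2-fold, 77.6% at 1.5-fold and 98% at 2-fold, and 4 of 128 calls were unchanged genes. Within males the recoveries were 6%, 36%, 69.4% and 91.8%, with 4 unchanged genes among 104 calls. Within females they were 2%, 38%, 71.4% and 87.8%, with 2 unchanged genes among 100 calls. No interaction was simulated, and the interaction test made 0 calls. The simulated genes were drawn independently, without differences shared by the genes of a library, so these rates may not hold for the real libraries.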

Results

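Gene expression in the thalamus was measured by RNA-seq in 31 adult mice at postnatal day 90, to ask whether it differed with the rearing of the mother. In 15 animals the mother had been reared in social isolation (SIR offspring, 7 males and 8 females), and 16 animals were control offspring (8 males and 8 females). Library totals ranged from 13 to 25.74 M (mega) estimated counts. Totals were 23.96 ± 1.09 M (SD, n = 8) in SIR females, 23.13 ± 2.04 (n = 7) in SIR males, 21.44 ± 3.85 (n = 8) in control females and 21.66 ± 3.18 (n = 8) in control males. The shallowest libraries were control female 31 (13 M) and control male 23 (14.81 M). After a filter on low counts, 14886 genes were tested.

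Transcripts of sex chromosome genes were examined as a test of the labels. Ddx3y, a Y-linked RNA helicase, stood at 41.8 ± 5.76 CPM (SD, n = 15) in libraries labelled male and at 0.0032 ± 0.0124 CPM (n = 15) in 15 of the 16 libraries labelled female. The library labelled SIR female 5 held 41.64 CPM of Ddx3y, 10.3 CPM of Eif2s3y and 7.79 CPM of Uty. Its level of the X-linked gene Eif2s3x, which escapes X inactivation, was 147.68 CPM, within the male range of 143.68 to 169.84 CPM and below the other females (212.01 to 259.76 CPM). It was kept in the group its label gives, and every direction in females below rests in part on that label. Its Fbln1 (23.59 CPM) and Zic5 (9.21 CPM) lay above the SIR males (13.45 to 16.96 and 3.17 to 6.18 CPM), among the SIR females. Its Tox (37.43 CPM) lay within the ranges of both. These genes were selected with this library among the females. Sex below therefore means the labelled sex, and the source of the mismatch was not settled. Without this library all 12 genes selected for females kept their direction and call, and the count of genes called in females was 543 in place of 688.

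**Figure D1:**
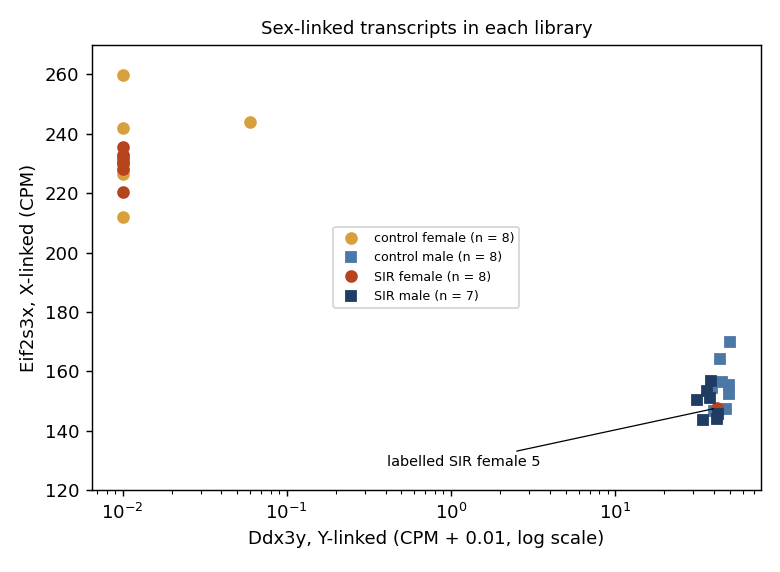
Level of the X-linked gene Eif2s3x (vertical axis, CPM) against that of the Y-linked gene Ddx3y (horizontal axis, CPM + 0.01, log scale), with each point a library coloured by housing and sex. The library labelled SIR female 5 lies among the males, at 41.64 CPM of Ddx3y and 147.68 CPM of Eif2s3x.

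The comparison of SIR and control offspring over both sexes takes the mean of the male and the female difference. A gene can pass it through a change in a single sex, so a call does not mean that both sexes changed. Within the sexes, no gene was called higher in both and 2 were called lower in both. Among the genes that rose in SIR offspring was Atat1, the alpha-tubulin acetyltransferase, by a log2 fold change of 0.14 ± 0.03 (SE, adjusted p = 0.0124), with 15 of 15 SIR libraries beyond the control median. The splicing factor Hnrnpl rose by 0.09 ± 0.02 (15 of 15 libraries). Cisd3, a mitochondrial iron-sulfur protein, rose by 0.20 ± 0.04, the AP-1 transcription factor Jund by 0.22 ± 0.05 and beta-synuclein (Sncb) by 0.16 ± 0.03, each with an adjusted p of 0.0124. Zmat5 (0.22), AI837181 (0.15), the proteasome subunit Psmb6 (0.14) and the proline synthesis enzyme Pycrl (0.17) rose as well. Pcdhgc4 rose by 0.43 ± 0.09 (1.35-fold, adjusted p = 0.0137, 12 of 15 libraries), and its value is uncertain because the genes of its protocadherin cluster share exons. Across the alternative settings its log2 fold change ran from 0.39 to 0.7. The noncoding RNA Particl rose by 0.24 ± 0.05 (15 of 15 libraries), which is uncertain because reads of an overlapping gene could have been counted in it.

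Of the genes that fell in SIR offspring, those with the smallest p-values are given first. The tyrosine kinase Abl2 fell by 0.15 ± 0.03 on the log2 scale, Atg2b, a lipid transfer protein of autophagy, fell by 0.19 ± 0.03 (15 of 15 libraries below the control median), and Bdp1, a subunit of the RNA polymerase III factor TFIIIB, fell by 0.25 ± 0.04. The X-linked postsynaptic scaffold gene Cnksr2 fell by 0.30 ± 0.06 and X-linked Lonrf3 by 0.29 ± 0.06 (13 of 15 libraries). Ankib1 (-0.14), Ylpm1 (-0.16), Stox2 (-0.16), Ankrd17 (-0.16) and the kinase Hipk3 (-0.18) were lower. The same held for the centrosomal gene Cep350 (-0.22) and the Golgi gene Trip11 (-0.21), and each of these 12 genes had an adjusted p of 0.0124. Single receptor genes fell in lists that were not called over both sexes. These were Grik2 (-0.19), 1 of 2 lower among 22 glutamate receptor genes (camera adjusted p = 0.194), and Gabrb2 (-0.27), 1 of 2 lower among 18 GABA receptor genes (0.0798). Chrm3 (-0.25) and Chrna7 (-0.31) were the 2 lower among 26 monoamine and acetylcholine receptor genes (0.413). The opioid receptor gene Oprm1 (-0.40 ± 0.11, adjusted p = 0.0372) was the 1 lower among 20 stress-hormone and neuropeptide receptor genes (camera adjusted p = 0.413).

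**Figure D2:**
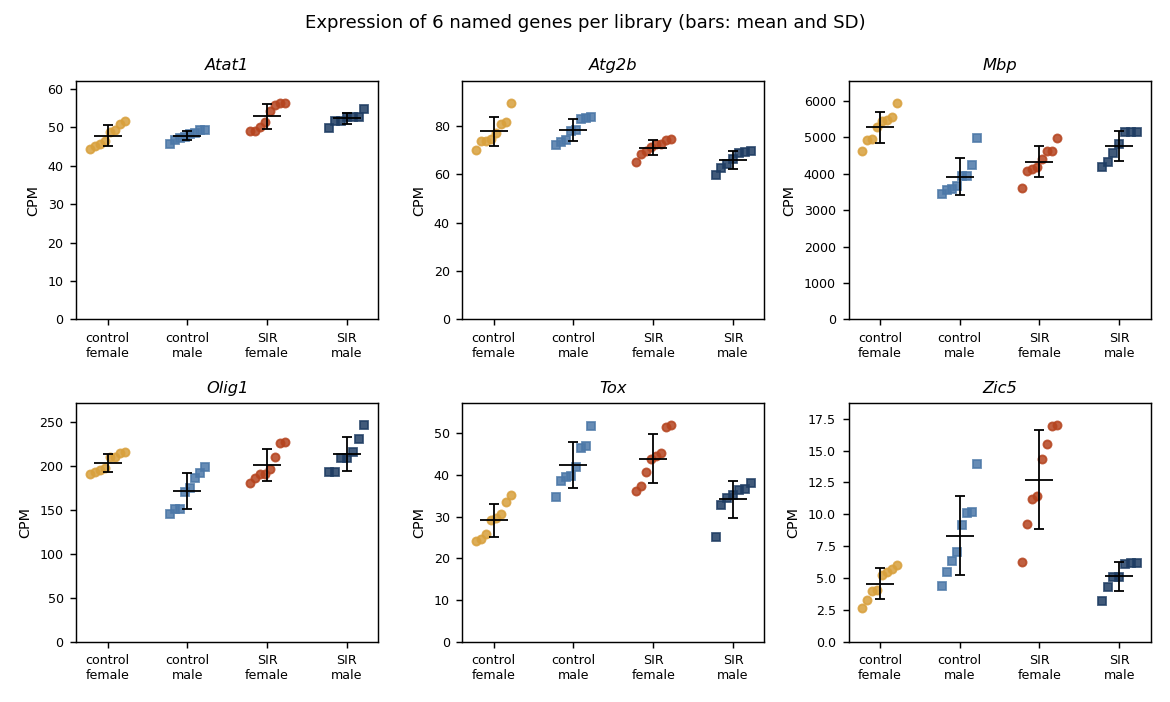
Level (CPM) of Atat1, Atg2b, Mbp, Olig1, Tox and Zic5 in each library, by housing and sex, with points ordered by value within a group and bars for the mean and SD. Atat1 lies higher and Atg2b lower in SIR offspring of both sexes, while Mbp, Tox and Zic5 shift in opposite directions in males and females.

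Of the gene lists, 5 of 38 differed over both sexes. Cytosolic ribosomal protein genes rose, with 12 of 44 members passing the gene test and 37 adjusted over the list alone. All 44 had positive fold changes, and the median log2 fold change was 0.116 (camera adjusted p = 5.59e-22, adjusted p = 0.588 with an estimated correlation). Rps15 (0.16), Rps3 (0.12), Rpl27 (0.15) and Rps29 (0.16) were among the 12. Single values are uncertain because ribosomal protein genes have near-identical pseudogenes with which reads could be shared. Nuclear-encoded genes of oxidative phosphorylation rose, with 6 of 48 members passing (32 adjusted over the list alone) and a median of 0.10 (adjusted p = 1.41e-17, adjusted p = 0.588 with an estimated correlation). Examples were Ndufs6 of complex I (0.23), Atp5e of the ATP synthase (0.16) and Cox4i1 of cytochrome oxidase (0.13). DNA methylation and chromatin enzymes fell (median -0.065, adjusted p = 0.0272, adjusted p = 0.588 with an estimated correlation), with 3 of 25 members lower (5 lower and 1 higher adjusted over the list alone), namely the acetyltransferase genes Ep300 (-0.15), Kat2b (-0.18) and Crebbp (-0.11). Without control male 25 the adjusted p of this list was 0.0502, and in all it lost its call under 5 of 39 alternative settings. With an estimated correlation, none of the 5 lists passed by camera, and 3 of 38 had an unadjusted p under 0.05, while fry called the ribosomal, oxidative phosphorylation, chromatin and neurotrophin lists, but not midbrain (0.0542) or choroid plexus markers (0.472).

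Markers of neighbouring regions moved in the same comparison, the midbrain markers mainly in females (median -2.973, against -0.011 in males). Midbrain and monoamine neuron markers fell (median -1.25), with 3 of 9 measured members lower (5 adjusted over the list alone; camera adjusted p = 0.0101, adjusted p = 0.646 with an estimated correlation), among them Pax7 and the dopamine transporter gene Slc6a3. Choroid plexus markers fell (median -0.838), with Prlr (-0.65) and Slc4a5 (-2.15) lower (camera adjusted p = 0.0272, adjusted p = 0.865 with an estimated correlation). The choroid plexus call was lost without SIR female 9 (adjusted p = 0.059) or control female 20 (adjusted p = 0.0819, where the median on the voom scale went from -0.51 to -0.225). With 3 components of the region markers in the model, the median on the voom scale was -0.034 for the midbrain list (adjusted p = 0.64) and -0.013 for the choroid plexus list (adjusted p = 0.655).

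Fold changes over both sexes also followed transcript length. Across genes, which are not independent replicates, the Spearman correlation of the log2 fold change with effective length was -0.326 over both sexes, -0.314 in males, -0.183 in females and -0.093 for the interaction. It was -0.262 for males against females, so the trend was not particular to housing. In the fifth of genes with the shortest transcripts (median 937 bases) 123 genes rose and 6 fell, and in the fifth with the longest (median 5264 bases) 9 rose and 240 fell. The slope of expression on log2 length per library was 0.029 ± 0.026 (SD, n = 8) in control females, 0.005 ± 0.022 (n = 8) in control males, 0.001 ± 0.017 (n = 8) in SIR females and -0.039 ± 0.024 (n = 7) in SIR males. The difference between SIR and control was -0.036 (permutation p = 0.00016, 2-sided, 100000 resamples). Ribosomal and oxidative phosphorylation transcripts are short. With the length trend removed, the ribosomal median on the voom scale went from 0.116 to 0.041 (adjusted p = 1.46e-05), the oxidative phosphorylation median from 0.099 to 0.032 (adjusted p = 0.00329) and the chromatin median from -0.074 to -0.028 (adjusted p = 0.478).

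**Figure D3:**
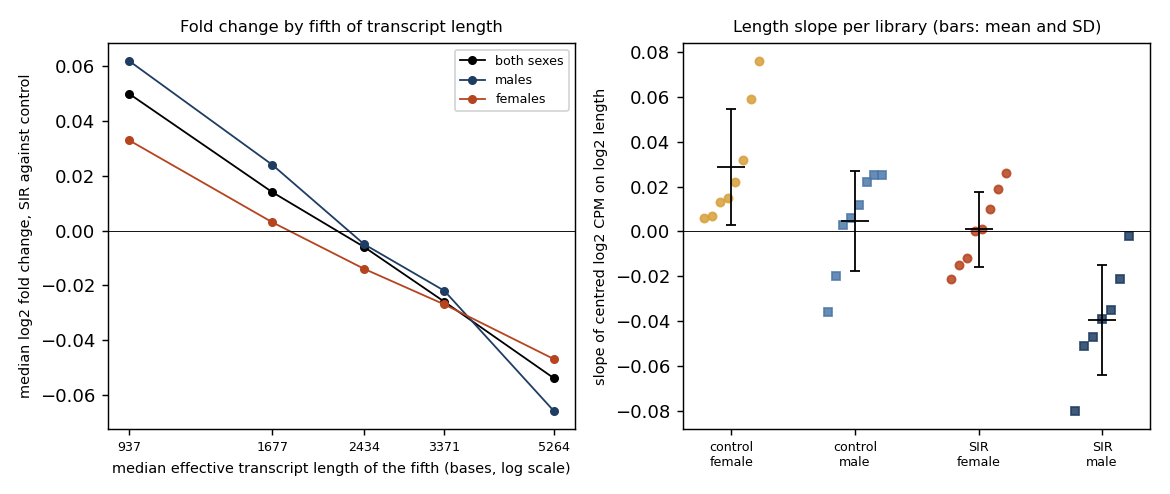
Left, median log2 fold change of SIR against control (vertical axis) in 5 equal groups of genes ordered by effective transcript length (horizontal axis, group median in bases, log scale), for both sexes, males and females. Right, slope of centred log2 CPM on log2 length in each library, with bars for the mean and SD, lowest in SIR males (mean -0.039).

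In all, 678 genes differed between SIR and control over both sexes by edgeR, 262 higher and 416 lower, with a median absolute log2 fold change of 0.16 and 8 genes above 1. With upper-quartile scaling 446 genes were higher and 306 lower. The count depended on single libraries and was 308 without SIR male 1, 299 without SIR female 3, 308 without the library labelled SIR female 5, 390 without SIR male 6, 434 without SIR female 12 and 273 without SIR male 15. It was 388 without control male 19, 1042 without control female 20, 344 without control male 21, 407 without control male 22, 220 without control male 25, 312 without control female 29, 284 without control female 30 and 415 without control female 31. With the length trend removed 78 genes were called, 73 of them among the 678, whose median absolute log2 fold change went from 0.155 to 0.117 (median SE 0.041 and 0.037). Of the named genes that rose, Cisd3 (0.12, adjusted p = 0.0668), Zmat5 (0.17, 0.0591), Psmb6 (0.08, 0.107) and Pycrl (0.15, 0.0517) lost their call there. Of those that fell, Abl2 (-0.07, 0.118), Stox2 (-0.07, 0.176) and Ankrd17 (-0.09, 0.0666) lost theirs. Ylpm1 (-0.11), Cep350 (-0.15) and Trip11 (-0.14) did so too, at an adjusted p of 0.0517 each. The fold change thus shrank much for some of these genes, such as Abl2, and little for others, such as Pycrl. With 3 components of the region markers 119 of the 678 were still called, with a median of 0.135 and a median SE of 0.051. There the log2 fold change was 0.11 for Atat1 (adjusted p = 0.0846), 0.18 for Cisd3 (0.0624), 0.09 for Sncb (0.171), 0.16 for Zmat5 (0.13), 0.13 for AI837181 (0.0717), 0.40 for Pcdhgc4 (0.0835), 0.13 for Psmb6 (0.066) and 0.17 for Pycrl (0.0613). Among the lower genes it was -0.23 for Cnksr2 (0.0549), -0.09 for Stox2 (0.128), -0.17 for Cep350 (0.0506) and -0.24 for Lonrf3 (0.0556). With the trend with GC content removed 148 genes were called, 124 of them among the 678. There the adjusted p was 0.0578 for Atat1, 0.0682 for Jund, 0.0581 for Sncb, 0.0501 for Particl, 0.109 for AI837181, 0.0642 for Pycrl, 0.0679 for Ankib1, 0.057 for Ylpm1 and 0.0835 for Ankrd17. On log2(TPM + 1) Hnrnpl (0.0541), Psmb6 (0.0701), Pycrl (0.0628), Abl2 (0.0618) and Cep350 (0.0664) lost their call, and after thinning Zmat5 did (0.0672). Without the 8 libraries whose numbers lie apart from the rest edgeR called 0 (2031 at an unadjusted p under 0.05, 380 by limma-voom, 219 by DESeq2). There the 24 genes selected by smallest p had an adjusted p of 0.0538 to 0.152, and the 677 of the 678 genes that were tested all kept their sign, with a median of 0.127 and a median SE of 0.043.

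In males, single genes such as Olig1 and Cd82 rose with maternal SIR, and others such as Rasal2 and Bdp1 fell. Olig1, a transcription factor of the oligodendrocyte lineage, rose by 0.32 ± 0.06 (1.25-fold, adjusted p = 0.0149, 7 of 7 SIR males beyond the control median), the tetraspanin gene Cd82 by 0.36 ± 0.07 and Hnrnpl by 0.15 ± 0.03. Mcrip1 (0.22, adjusted p = 0.0206), Fam234a (0.24) and Wbp1 (0.33, both with an adjusted p of 0.0216) rose in 7 of 7 SIR males. The Ras regulator Rasal2 fell by 0.30 ± 0.05, Bdp1 by 0.35 ± 0.06 and the ubiquitin ligase gene Ubr3 by 0.26 ± 0.05. Gigyf2 fell by 0.21 ± 0.04, Atg2b by 0.25 ± 0.05 and the protocadherin gene Pcdh10 by 0.21 ± 0.04 (adjusted p = 0.0149 for these 6 genes, 7 of 7 SIR males each). Oprm1, the mu opioid receptor gene, fell by 0.85 ± 0.16 (1.81-fold, adjusted p = 0.0149), the presynaptic gene Pclo by 0.36 ± 0.07 and the sodium channel gene Scn2a by 0.38 ± 0.09. They were named as members of lists that were not called in males. The lists held 20 stress-hormone and neuropeptide receptor, 21 synaptic vesicle and 28 thalamic ion channel genes. Oprm1, Pclo and Scn2a were not followed through the alternative settings, such as removal of the length trend.

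Of the lists, 16 of 38 differed in males by camera, 10 higher and 6 lower. The oligodendrocyte and myelin list rose by a median of 0.222 with 23 of 23 positive values (camera adjusted p = 4.03e-12, adjusted p = 0.219 with an estimated correlation), where Plekhb1 (0.24), Mbp (0.28) and Cnp (0.22) passed the gene test and 15 passed adjusted over the list alone. Mural and leptomeningeal markers rose by a median of 0.263, with no member passing (5 adjusted over the list alone; adjusted p = 1.12e-06, adjusted p = 0.175 with an estimated correlation). Ribosomal protein genes (0.124, adjusted p = 3.93e-15) and oxidative phosphorylation genes (0.12, adjusted p = 3.34e-13) rose too, with no member passing (12 and 0 adjusted over the list alone), each at an adjusted p of 0.321 with an estimated correlation. Higher medians were also found for markers of oligodendrocyte precursors (0.119, adjusted p = 0.00277), microglia (0.121, adjusted p = 0.000151), endothelial cells (0.096, adjusted p = 0.00277) and astrocytes (0.091, adjusted p = 0.00934), and for interferon response (0.227, adjusted p = 0.000759) and immediate early genes (0.205, adjusted p = 0.0124). Of these 6 lists, Olig1 and the astrocyte gene S100b (0.23) were the members that passed (3 precursor, 1 microglial, 3 endothelial and 2 astrocyte genes adjusted over the list alone). The 6 lists had an adjusted p of 0.219 to 0.545 with an estimated correlation. Glutamate receptor genes fell (median -0.117, 1 of 22 lower, Grik2, and 6 adjusted over the list alone; adjusted p = 0.000741, adjusted p = 0.175 with an estimated correlation) and GABA receptor genes fell (median -0.149, Gabrb1 -0.23, 2 lower adjusted over the list alone; adjusted p = 0.00277, adjusted p = 0.219 with an estimated correlation). Genes of cholesterol synthesis (median -0.093, adjusted p = 0.00277), chromatin enzymes (-0.075, adjusted p = 0.00753), the circadian clock (-0.096, adjusted p = 0.012) and thalamic relay neurons (-0.126, adjusted p = 0.0156) were lower as lists, with Crebbp (-0.19), Nr1d2 (-0.30) and Necab1 (-0.79) among the members passing. Adjusted over the list alone, 0, 4, 1 and 1 of their members were lower, in that order. None of the 16 passed with an estimated correlation (adjusted p = 0.175 to 0.654, and 6 of 38 lists under an unadjusted p of 0.05), and fry called 6.

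Several male list calls rested on single libraries. The relay neuron list lost its call without SIR male 1 (adjusted p = 0.0736), SIR male 4 (0.118), SIR male 6 (0.0593), SIR male 13 (0.129) or control male 16 (0.162). The immediate early genes lost theirs without SIR male 14 (0.0528), SIR male 15 (0.0926), control male 19 (0.1) or control male 27 (0.0525). Without one library the adjusted p was 0.0531 for astrocytes (SIR male 15), 0.177 for cholesterol synthesis (SIR male 14) and 0.0637 for the circadian clock (SIR male 4). On the voom scale 1 library moved the median from -0.15 to -0.087 for relay neurons (SIR male 4), from -0.094 to -0.047 for cholesterol synthesis (SIR male 14) and from 0.183 to 0.301 for immediate early genes (SIR male 4). It went from -0.098 to -0.065 for the circadian clock (control male 21 or control male 22) and from -0.072 to -0.047 for chromatin enzymes (control male 25). With the length trend removed the adjusted p was 0.268 for chromatin enzymes and 0.0515 for the circadian clock. The median on the voom scale there went from 0.124 to 0.036 for ribosomal protein genes (adjusted p = 0.0125), from 0.119 to 0.028 for oxidative phosphorylation genes (adjusted p = 0.0317) and from -0.123 to -0.054 for glutamate receptors (adjusted p = 0.0317). Midbrain markers were at -0.13 ± 0.95 (list score, SD, n = 7) in SIR males and 0.13 ± 0.50 (n = 8) in control males.

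In males 198 genes were called by edgeR, 42 higher and 156 lower, with 2622 at an unadjusted p under 0.05. With upper-quartile scaling 110 were higher and 94 lower. The count was 50 without SIR male 1, 23 without SIR male 6, 17 without SIR male 15, 93 without control male 19, 38 without control male 21, 26 without control male 25. It was 506 without control male 27, 314 without control male 28 and 325 without control female 31. Without control male 22 edgeR called 0 genes in males (2193 at an unadjusted p under 0.05, 91 by limma-voom, 288 by DESeq2). There all 12 genes named first for males had an adjusted p of 0.0516 to 0.061, and all 198 genes kept their sign. Without SIR male 15, 8 of the 12 had an adjusted p of 0.0509 to 0.0549. Mcrip1 was lost also without SIR male 1 (0.0603), SIR male 6 (0.0551) or control male 25 (0.0615). Fam234a was lost without SIR male 6 (0.0551) or control male 25 (0.0549), and Wbp1 without SIR male 1 (0.0568), control male 21 (0.0514) or control male 25 (0.0569). With the length trend removed 36 genes were called in males. There Mcrip1 (log2 fold change 0.18, adjusted p = 0.0785), Wbp1 (0.30, 0.0591), Atg2b (-0.18, 0.0602) and Pcdh10 (-0.16, 0.0654) lost their call. With the GC trend removed 82 genes were called, and Mcrip1 (0.0751) and Fam234a (0.0641) lost theirs. On log2(TPM + 1) the adjusted p was 0.464 for Fam234a (0.16), 0.17 for Wbp1 (0.24), 0.129 for Ubr3 (-0.23), 0.0917 for Pcdh10 (-0.25) and 0.0541 to 0.0731 for Hnrnpl, Mcrip1, Rasal2, Bdp1, Gigyf2 and Atg2b. With transcript length offsets it was 0.333 for Fam234a (0.22), 0.0932 for Wbp1 (0.30), 0.145 for Ubr3 (-0.19), 0.0813 for Pcdh10 (-0.21), 0.0693 for Gigyf2 and 0.057 for Bdp1. From the male libraries alone it was 0.0523 for Olig1, 0.0593 for Mcrip1 and 0.065 for Fam234a.

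In females, single genes such as Fbln1 and Zic5 rose with maternal SIR, and others such as Elmod1 and Lmx1a fell. The extracellular matrix gene Fbln1 rose from 14.3 ± 3.12 CPM (SD, n = 8) in control females to 28.3 ± 5.26 CPM (n = 8) in SIR females, a log2 fold change of 0.98 ± 0.14 (SE; 1.97-fold, adjusted p = 0.000706). Prokr2, a receptor of prokineticin, rose by 1.62 ± 0.25 (3.08-fold) and the zinc finger gene Zic5 by 1.47 ± 0.22 (2.77-fold). Slc41a3 rose by 0.70 ± 0.11, the transcription factor gene Tox by 0.59 ± 0.09 and the glycosyltransferase gene Mgat5b by 0.46 ± 0.07, and these 5 genes had an adjusted p of 0.000706 and were higher in 8 of 8 SIR females. The glutamate receptor genes Grm2 (0.78) and Grin2d (0.42) rose, 2 of 22 in a list that was not called (camera adjusted p = 0.615). The calcium-binding protein gene Calb2 (0.71) rose, 1 of 3 higher among 20 thalamic relay neuron markers, which were not called either (0.0835). Elmod1 fell by 0.37 ± 0.06 (adjusted p = 0.000706), the transcription factor gene Pou3f3 by 0.43 ± 0.07 (adjusted p = 0.000706) and Spg20 by 0.25 ± 0.04 (adjusted p = 0.00116), each in 8 of 8 SIR females. Lmx1a fell from 1.37 ± 1.03 CPM (SD, n = 8) to 0.0732 ± 0.0631 CPM (n = 8; adjusted p = 0.000706).

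Of the lists, 9 of 38 differed in females by camera, 3 higher and 6 lower. The oligodendrocyte and myelin list fell (median -0.257), with 10 of 23 members lower (18 adjusted over the list alone) and 22 of 23 negative (camera adjusted p = 1.62e-12, adjusted p = 0.41 with an estimated correlation). Mobp fell by 0.36 ± 0.08, Ermn by 0.41 ± 0.10, Myrf, a transcription factor of myelination, by 0.31 ± 0.07 and Mbp by 0.29 ± 0.07. Cholesterol synthesis genes rose by a median of 0.175, with 6 of 22 higher (15 adjusted over the list alone; adjusted p = 2.45e-09, adjusted p = 0.41 with an estimated correlation), among them Mvd (0.30), Hsd17b7 (0.36), Hmgcs1 (0.20) and the regulator Srebf2 (0.15). Ribosomal protein genes (0.106, adjusted p = 1.08e-10, adjusted p = 0.567 with an estimated correlation) rose, with 1 member passing and 3 genes adjusted over the list alone. Oxidative phosphorylation genes rose with no member passing (0.082, adjusted p = 1.12e-07, adjusted p = 0.606 with an estimated correlation). Mural and leptomeningeal markers fell (median -0.235, adjusted p = 0.00363, adjusted p = 0.469 with an estimated correlation), with Tagln (-0.52), Acta2 (-0.48), Mgp (-0.52) and Col3a1 (-0.59) lower (the same number, 4, adjusted over the list alone). Heat shock protein genes fell (median -0.10) with no member passing (adjusted p = 0.00157, adjusted p = 0.606 with an estimated correlation). Inflammatory signalling genes fell (median -0.203, adjusted p = 0.033, adjusted p = 0.421 with an estimated correlation), with the chemokine gene Ccl3 lower (-1.69). None of the 9 lists passed with an estimated correlation (4 of 38 at an unadjusted p under 0.05). Fry called 4 of the 9 (myelin, cholesterol synthesis, inflammatory and midbrain) and, outside them, neurotrophins (adjusted p = 0.0131). With the length trend removed the median on the voom scale went from 0.113 to 0.052 for ribosomal protein genes (adjusted p = 0.000264) and from 0.078 to 0.034 for oxidative phosphorylation genes (adjusted p = 0.035).

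Region markers moved with housing in females. Midbrain and monoamine neuron markers fell (median -2.973), with 5 of 9 measured members lower (6 adjusted over the list alone; adjusted p = 0.0014, adjusted p = 0.41 with an estimated correlation), among them Slc6a3, Pax7, Foxa1 and Barhl1. The midbrain list score was 0.85 ± 0.92 (SD, n = 8) in control females and -0.87 ± 0.33 (n = 8) in SIR females, and 0.13 ± 0.50 (n = 8) in control males. Choroid plexus markers fell (median -1.489), with Slc4a5 and Prlr lower (12 adjusted over the list alone; adjusted p = 0.00363, adjusted p = 0.844 with an estimated correlation), and without control female 20, whose score was 4.12, the adjusted p was 0.227 and the median on the voom scale went from -0.719 to -0.275. The inflammatory list lost its call without SIR female 11 (0.06), SIR female 12 (0.0571), control female 18 (0.073), control female 20 (0.202) or control female 26 (0.0752), and its median on the voom scale went from -0.176 to -0.06 without control female 20. With 3 components of the region markers in the model, the adjusted p was 0.05 for Zic5 (0.87), 0.081 for Slc41a3 (0.45), 0.0531 for Elmod1 (-0.26), 0.22 for Lmx1a (-1.48) and 0.113 for Pou3f3 (-0.26). In that model the list of mural markers was at -0.033 on the voom scale (adjusted p = 0.572), inflammatory genes at -0.097 (0.123), midbrain markers at 0.098 (0.705), choroid plexus markers at -0.009 (0.769) and oxidative phosphorylation genes at 0.000 (0.908), while myelin genes stayed lower (-0.242).

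**Figure D4:**
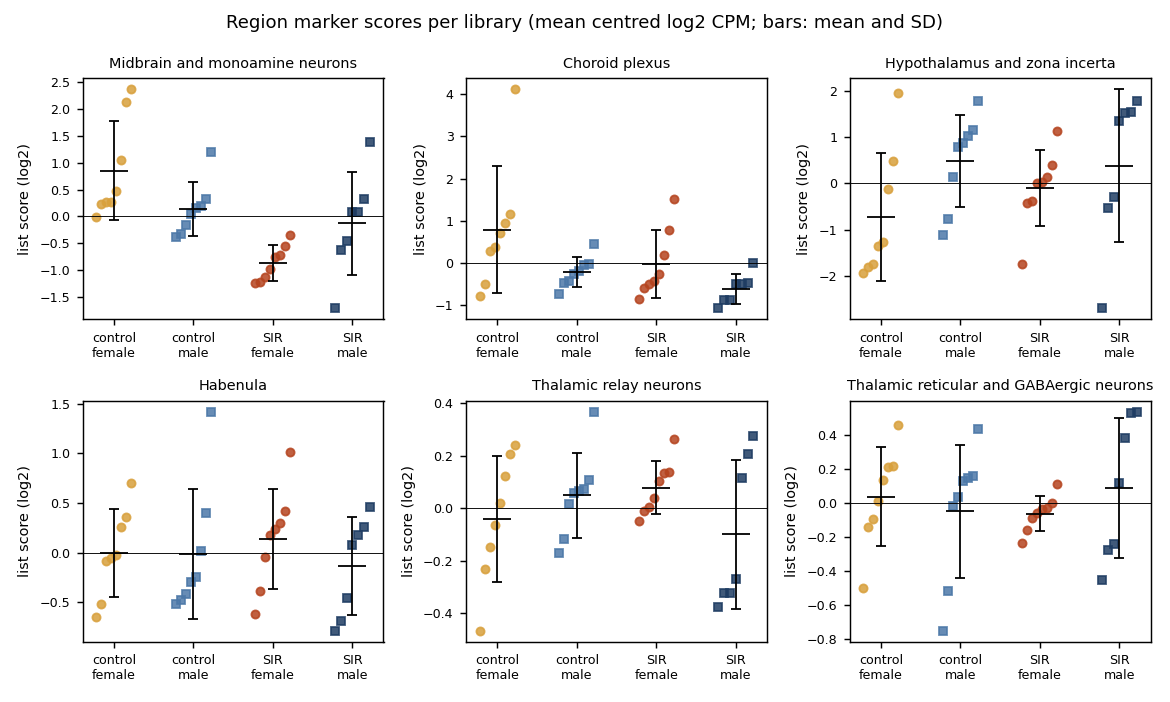
List score (mean centred log2 CPM, vertical axis) of 6 region marker lists in each library, by housing and sex, with points ordered by value and bars for the mean and SD. Midbrain scores lie between -1.24 and -0.34 in SIR females and between -0.01 and 2.36 in control females, and control female 20 has a choroid plexus score of 4.12.

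In females 688 genes were called by edgeR, 355 higher and 333 lower, with a median absolute log2 fold change of 0.29 and 67 genes above 1. The count was 360 without SIR female 3, 381 without SIR female 7, 365 without control female 29 and 428 without control female 31. Without the 8 libraries whose numbers lie apart 45 genes were called, 41 of them among the 688, and Pou3f3 (-0.34, adjusted p = 0.071) was not among them. The 686 of the 688 genes that were tested there all kept their sign, with a median absolute log2 fold change of 0.236 in place of 0.288 and a median SE of 0.085 in place of 0.075.

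The interaction asks whether the difference between SIR and control offspring itself differed between males and females, and myelin genes showed the strongest list result. Mbp, the main basic protein of myelin, stood at 5280 ± 422 CPM (SD, n = 8) in control females and 4330 ± 426 CPM (n = 8) in SIR females, but at 3920 ± 502 CPM (n = 8) in control males and 4760 ± 411 CPM (n = 7) in SIR males. Its interaction was 0.57 ± 0.10 on the log2 scale (SE, adjusted p = 0.00134), where a positive value means a higher SIR effect in males. Cd82 (0.66 ± 0.10) and Fam234a (0.48 ± 0.07) were positive, both with an adjusted p of 0.000773, and Fam234a lost its call with transcript length offsets (0.48, adjusted p = 0.11) and on log2(TPM + 1) (0.41, adjusted p = 0.163). Prr18 (0.59, 0.000904), the sphingosine phosphate receptor gene S1pr5 (0.74, 0.000987) and apolipoprotein D (Apod, 0.72 ± 0.13, 0.00134) were positive too. The heparan sulfate enzyme gene Ndst1 (-0.38), Tox (-0.91 ± 0.13), Zic5 (-2.17 ± 0.31) and the formin gene Fhod3 (-0.51) were negative at an adjusted p of 0.000552. Negative too were the transcription factor gene Lhx9 (-1.14 ± 0.18, 0.000773) and Grin2d (-0.61 ± 0.10, 0.000886). Tox stood at 29.1 ± 3.99 CPM in control females (n = 8), 43.9 ± 5.82 in SIR females (n = 8), 42.4 ± 5.50 in control males (n = 8) and 34.1 ± 4.35 in SIR males (n = 7).

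Of the lists, 17 of 38 had an interaction by camera, 11 positive and 6 negative. The oligodendrocyte and myelin list had a median of 0.41 with 23 of 23 positive values, where 16 members passed the gene test and 20 adjusted over the list alone (camera adjusted p = 7.75e-25, adjusted p = 0.0491 with an estimated correlation). Mural and leptomeningeal markers had a median of 0.555 with 4 of 17 members passing (8 adjusted over the list alone; adjusted p = 4.52e-09, adjusted p = 0.0491 with an estimated correlation), namely Acta2 (0.95), Col3a1 (1.13), Tagln (0.85) and Mgp (0.84). The myelin and mural lists were the only ones of the 17 to pass with an estimated correlation, and fry called 7. The mural list kept its call in the 8 settings run for lists and without each single library, but its median was as low as 0.274 on the voom scale. No list call was tested without the 8 libraries whose numbers lie apart. Cholesterol synthesis genes had a median of -0.259 with 7 of 22 lower (17 adjusted over the list alone; adjusted p = 3.05e-11, adjusted p = 0.0933 with an estimated correlation), among them Hmgcs1 (-0.37). Oligodendrocyte precursor markers had a median of 0.214 (adjusted p = 0.000904, adjusted p = 0.0933 with an estimated correlation), with Bcas1 (0.61), Sox10 (0.46) and Olig1 (0.34) higher and Cacng4 (-0.26) lower (7 and 1 adjusted over the list alone). Glutamate receptor genes had a median of -0.115 (adjusted p = 0.00273, adjusted p = 0.0933 with an estimated correlation), with Grm2 (-1.13), Grin2d and Grin3a (-0.45) passing (3 adjusted over the list alone). Thalamic relay neuron markers were at -0.132 (adjusted p = 0.00224, adjusted p = 0.574 with an estimated correlation), with Necab1 (-1.63), Gbx2 (-0.95) and Calb2 (-0.89) passing (4 adjusted over the list alone), and at -0.081 on the voom scale with 3 region components (adjusted p = 0.0999). Without these components single libraries moved the voom-scale median from -0.174 to -0.262 (without SIR male 14) or -0.101 (without control female 20).

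**Figure D5:**
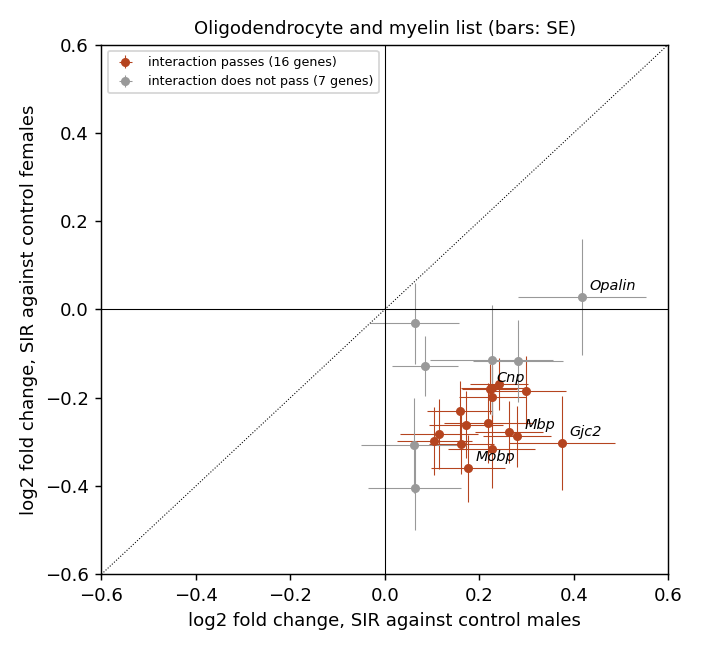
Log2 fold change of SIR against control in females (vertical axis) against that in males (horizontal axis) for the 23 genes of the oligodendrocyte and myelin list, with bars for the SE and the 16 genes with an interaction in red. The genes lie at positive values in males and, with 1 exception, at negative values in females.

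By edgeR, 422 genes had an interaction, 161 positive and 261 negative (219 and 225 with upper-quartile scaling), with 2284 at an unadjusted p under 0.05, and no single library moved the count by over 1.5 times. Across genes, which are not independent replicates, log2 fold changes in males and females had a Pearson correlation of -0.045 and a Spearman correlation of 0.045, and 55.2% had the same sign. No gene was called higher in both sexes (1 for independent lists) and 2 were called lower in both (3.5 for independent lists). A total of 5 genes were higher in males and lower in females (0.9 for independent lists), and 6 were lower in males and higher in females (3.7 for independent lists).

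Males and females were compared over both housing groups, with the library labelled SIR female 5 among the females. Prpf19, a splicing factor, was higher in males by 0.15 ± 0.02 (SE, adjusted p = 2.77e-05, 15 of 15 males beyond the female median), and the cold-inducible RNA-binding protein gene Cirbp by 0.67 ± 0.10. Also higher were the natriuretic peptide receptor gene Npr1 (0.81 ± 0.13), the ion channel gene Asic2 (0.24), Pspc1 (0.23) and Flywch2 (0.36). Lower in males were Hhip, an inhibitor of hedgehog signalling (-0.45 ± 0.06, adjusted p = 2.27e-05), the kinase gene Lrrk2 (-0.29), Ldlrad4 (-0.23), the neuregulin receptor gene Erbb3 (-0.41), Cpd (-0.25) and the transcription factor gene Zeb2 (-0.33). Lrrk2 lost its call with transcript length offsets (-0.19, adjusted p = 0.266) and on log2(TPM + 1) (-0.18, adjusted p = 0.322), where Prpf19 (0.13, adjusted p = 0.0883) and Pspc1 (0.24, adjusted p = 0.0644) lost theirs too. The X-linked genes Eif2s3x (-0.57 ± 0.04, adjusted p = 2.72e-10), Kdm6a (-0.57), Kdm5c (-0.44), Ddx3x (-0.45) and Pbdc1 (-0.34) were lower in males, while Utp14a (adjusted p = 0.209), Usp9x (0.22) and Mid1 (0.816) did not differ by the test. The Y-linked genes Ddx3y (7.40), Eif2s3y (5.60) and Uty (4.91) were higher, by values that the library labelled SIR female 5 lowered (12.33, 8.71 and 6.79 without it). Kdm5d (3.65) and Uba1y (1.47) were higher too, and both are uncertain because reads could be shared with their similar X-linked copies. In all, 1502 genes differed, 661 higher and 841 lower in males. In the fifth of genes with the shortest transcripts 244 were higher and 39 lower, and in the fifth with the longest 37 were higher and 383 lower. With the length trend removed 1059 genes were called, 888 of them among the 1502.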

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

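The removal of the length and GC trends, the thinning to 1 depth, the 3 region components and the test of handling alike in both sexes were chosen only after the results they bear on were seen. In 472 groups of libraries tested for a library far from the others, 34 were found, and chance alone gives about 1 in 20, or 24.

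The library labelled SIR female 5 stood apart from the other SIR females in 8 sex-linked genes, on the log2 CPM scale: Ddx3y 5.38, Eif2s3y 3.38, Kdm5d 3.96, Uty 2.98, Uba1y 1.28, Kdm5c 6.32, Ddx3x 7.40 and Eif2s3x 7.21. Control female 29 stood apart in Ddx3y (-2.86, at 0.05 CPM) and Grin2d (5.55), control female 30 in Uba1y (-0.29) and in the chromatin enzyme score (0.13), and SIR male 6 in Eif2s3y (2.42). Control female 20 was apart in the scores of choroid plexus (4.12), ependymal cells (1.47), interferon response (0.45) and striatum (0.92) and in Bdp1 (4.78). SIR male 14 was apart in the cholesterol score (-0.33) and in Jund (7.13), Tox (4.65), Ldlrad4 (4.38) and Kdm5c (6.42). SIR male 1 was apart in the glutamate receptor score (-0.21) and Fhod3 (5.53), control male 21 in the heat shock score (-0.34) and control male 27 in the midbrain score (1.2). The others were Pycrl in control male 19 (3.86), Ankib1 in SIR male 8 (5.94), Elmod1 in SIR female 9 (6.80), Pou3f3 in control male 23 (5.92) and Zeb2 in SIR female 2 (5.77). In depth, control female 31 (13 M counts) and control male 23 (14.81) lay below their groups.

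The SIR effect differed between males and females in 422 genes by the interaction test. The named genes were Cd82 (0.66), Fam234a (0.48), Prr18 (0.59), S1pr5 (0.74), Mbp (0.57), Apod (0.72), Ndst1 (-0.38), Tox (-0.91), Zic5 (-2.17), Fhod3 (-0.51), Lhx9 (-1.14) and Grin2d (-0.61). The lists, by median, were myelin (0.41), mural and leptomeningeal cells (0.555), cholesterol synthesis (-0.259), oligodendrocyte precursors (0.214), glutamate receptors (-0.115) and thalamic relay neurons (-0.132), described above, and 11 others. Of these 11, interferon response (0.293, camera adjusted p = 0.000904), microglia (0.117, 0.00185), inflammatory signalling (0.288, 0.00394), heat shock proteins (0.093, 0.00394), the circadian clock (-0.149, 0.00869) and cerebral cortex (-0.169, 0.0131) kept their call without each single library. With 3 region components the circadian list had an adjusted p of 0.416. With an estimated correlation these 6 had an adjusted p of 0.121 to 0.537. At an adjusted p of 0.0492 stood immediate early genes (0.271), endothelial cells (0.089), GABA receptors (-0.069), midbrain neurons (2.995) and the unfolded protein response (0.106). These 5 were lost without many of the 31 libraries taken in turn: 12 for immediate early genes (highest adjusted p 0.169, without control female 26), 19 for endothelial cells (0.152, control male 25), 16 for GABA receptors (0.0971, control female 18), 14 for midbrain neurons (0.114, SIR male 4) and 16 for the unfolded protein response (0.122, control male 21). With an estimated correlation they had an adjusted p of 0.447 to 0.606. On the voom scale 1 library moved the median from -0.124 to -0.075 for GABA receptors (SIR male 1), from 0.258 to 0.142 for immediate early genes (control female 26) and from 1.949 to 1.294 for midbrain neurons (control female 29). With 3 region components the midbrain median turned negative, down to -0.052 on the voom scale.

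Long transcripts were lower and short ones higher in SIR offspring over both sexes. The library labelled SIR female 5 is argued against by the correlation of fold change and length across genes without it (-0.321, against -0.326). GC content is argued against by the correlation with its trend removed (-0.373). Thinning to 1 depth gave -0.338, but thinning keeps each gene's expected share of a library, so it cannot decide whether depth is the cause. Without the 2 shallowest libraries the correlation was -0.317, which argues against these 2 libraries as its source. A length-dependent shift of whole libraries, such as RNA integrity or library preparation would bring, may account for part of the calls, since 73 of the 678 genes were still called with the trend removed, among 78 in all. The 678 genes all kept their direction there, but their median absolute log2 fold change went from 0.155 to 0.117 with an SE of 0.041 before and 0.037 after, and the smaller fold changes ended the calls. Removing the GC trend did nearly the same to the calls (124 of the 678 still called, 0.117, SE 0.037), so the loss of calls does not single out length. The correlation with length was -0.262 for males against females as well. Removing the trend takes away a biological change of long or short transcripts as well, so a change with maternal SIR stays open and untested.

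In females, markers of midbrain and choroid plexus were lower in SIR offspring and region genes were among the strongest calls. The library labelled SIR female 5 is argued against as the source, since 543 genes were called without it. With 3 region components 480 genes were called, above the bound written beforehand against a difference in the extent of dissection. That bound was wrong, because the components are built from the region markers themselves and 125 of the 688 genes stayed called, with a median log2 fold change of 0.22 in place of 0.288 and an SE of 0.097 in place of 0.075. A difference in dissection and a change of these cells with maternal SIR cannot be told apart here, since dissection dates and tissue weights were not used here.

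Myelin genes were higher in SIR males and lower in SIR females, with a median interaction of 0.41. The median was 0.433 without the library labelled SIR female 5 and 0.409 with the length trend removed, which argues against each of these as its cause. With 3 region components it was 0.416, which argues only against the neighbouring regions that these components mark. The components hold none of the 23 genes, so they cannot decide whether the dissection differed in white matter. Handling that shifted both sexes alike between the number ranges of the housing groups is argued against too, since each range holds both sexes and the median was 0.222 in males (23 of 23 positive) and -0.257 in females (22 of 23 negative). The share of white matter in the tissue, litters and handling that differed by sex stay open, since no region list holds these genes and the labels give no litters or batches. A sex-dependent change in oligodendrocytes with maternal SIR stays open as a hypothesis too, untested here, and myelin staining in matched sections could test it.

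Splits of the libraries into other groups of the same sizes were drawn 100 times for each count, the real one included. In each of the 5 comparisons 1 split, the real one, gave as many genes, which argues against random grouping of independent animals. The splits moved single animals, so chance differences between litters or between number ranges of the housing groups are not excluded. For the interaction they also removed the housing difference within each sex, so they do not test the interaction alone. The real and highest other values were 678 and 1 over both sexes, 198 and 2 in males, 688 and 32 in females, 422 and 2 for the interaction, and 1502 and 25 for males against females.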

How the results depend on the processing

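Leaving out the 2 shallowest libraries, removing length or GC trends, thinning, the 3 region components, and these components without the library labelled SIR female 5 were chosen after seeing the data. No paired analysis was possible because replicate numbers are unique across the groups. The 82 selected gene results kept their direction in all 1625 values under 21 settings, and 118 of these no longer passed. For lists 8 settings were run. Of 373 values of 47 list calls, 260 kept call and direction, 103 no longer passed and 10 changed direction. List calls were not tested on log2(TPM + 1), with the GC trend removed or without the 2 shallowest libraries. Nor were they tested without the 8 libraries whose numbers lie apart. Without each library in turn, 28 of 2542 gene values and 98 of 1457 list values no longer passed, and none reversed. At these depths and numbers, changes of 1.1-fold were mostly missed on simulated data (18% recovered over both sexes).

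Counts of genes that moved by over 1.5 times are given by comparison, and the cause was not tested except where fewer samples, more genes or a looser threshold set it. Over both sexes (678) there were 382 with no filter, 1159 by DESeq2, 1250 by limma-voom, 319 on log2(TPM + 1), 1214 with 1 region component, 0 by edgeR without the 8 libraries whose numbers lie apart (2031 at an unadjusted p under 0.05, 380 by limma-voom, 219 by DESeq2) and 1498 at a threshold of 0.1. Added settings gave 392 without the 2 shallowest libraries, 78 without the length trend, 148 without the GC trend and 448 with 3 components and no SIR female 5. In males (198) there were 79 with no filter, 626 by DESeq2, 627 by limma-voom, 98 on log2(TPM + 1), 996 with 2 surrogate variables, 647 with 1 component, 76 from the male libraries alone, 542 without the 8 libraries and 682 at 0.1. Added settings gave 379 without the 2 shallowest, 36 without the length trend, 82 without the GC trend, 840 with 3 components and 884 with these and no SIR female 5. In females (688) there were 1217 by limma-voom, 268 on log2(TPM + 1), 1085 with 1 component, 45 without the 8 libraries, 1256 at 0.1 and 458 without the 2 shallowest. The interaction (422) had 740 by limma-voom, 277 with transcript length offsets, 230 on log2(TPM + 1), 896 with 2 surrogate variables, 705 with 1 component, 720 at 0.1 and 712 with 3 components and no SIR female 5. Males against females (1502) had 3019 by limma-voom, 678 on log2(TPM + 1), 2506 with 2 surrogate variables, 516 without the 8 libraries, 2490 at 0.1, 660 with 3 components and 671 with these and no SIR female 5.

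Leaving out 1 library gave 220 (control male 25) to 1042 (control female 20) genes over both sexes, 0 (control male 22; 2193 at an unadjusted p under 0.05, 91 by limma-voom, 288 by DESeq2) to 506 (control male 27) in males, 360 (SIR female 3) to 829 (control female 20) in females, 285 to 532 for the interaction and 1045 to 2200 for males against females. The counts of lists ran from 4 (SIR female 9) to 9 (SIR male 14) over both sexes, with 8 without SIR male 4 or control female 18, from 15 to 17 in males, 7 to 11 in females and 12 to 19 for the interaction.

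Lists called by camera with an estimated correlation were 0 of 38 over both sexes, 0 in males, 0 in females and 2 for the interaction (3, 6, 4 and 7 at an unadjusted p under 0.05). Fry called 6 in males, 5 in females (1 of them not called by camera) and 7 for the interaction. Over both sexes (5) there were 12 with 2 surrogate variables, 2 with the stricter filter, 12 with 3 components and 11 with these and no SIR female 5. Directions turned only with 3 region components, and the medians given for this are on the voom scale, first with all libraries and then without SIR female 5. Choroid plexus over both sexes was at -0.013 and -0.031, from -0.51, where the test's direction turned. Choroid plexus in females was at -0.009 and 0.039 (from -0.719), midbrain markers in females at 0.098 and 0.127 (from -2.232), oxidative phosphorylation in females at 0.000 and -0.016 (from 0.078), and the midbrain interaction at -0.048 and -0.052 (from 1.949). For the region lists the components are built from their own scores; for oxidative phosphorylation the cause was not tested.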

Other observations

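The comparison of males and females within each housing group, that in SIR offspring without the library labelled SIR female 5, and the settings with 3 region components were chosen after the results were seen.

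Single members of lists that were not called by camera differed in females with maternal SIR. The genes named in this paragraph were not followed through the alternative settings. Of all 688 genes called in females, 125 stayed called with 3 region components and 41 without the 8 libraries whose numbers lie apart. A difference in dissection is thus not excluded for them. Of 21 synaptic vesicle genes (camera adjusted p = 0.937), 5 passed and went both ways: Cplx2 (-0.83), Syt2 (-0.67), Sv2c (-0.69) and Vamp1 (-0.36) fell and the synapsin gene Syn2 (0.35) rose. Of 18 neurotrophins and growth factors (0.102), Bdnf (-0.57), Vgf (-0.40), Nrg1 (-0.42) and Igf1 (-0.48) fell in females and Gdnf (1.32) rose. Of 26 monoamine and acetylcholine receptor genes (0.937), Htr1b (-0.94) and Chrna7 (-0.44) fell, and of 20 stress-hormone and neuropeptide receptor genes (0.97), Galr1 (1.16) rose. In other lists not called, the habenula marker Gpr151 (1.88), Tbr1 (1.05), Stx1a (0.41), C1ql2 (1.1) and Syndig1l (0.59) rose, and Tal1 (-1.26) and the endoplasmic reticulum chaperone gene Hspa5 (-0.25) fell. Of 18 circadian clock genes (0.381), Bhlhe40 (0.28), Nr1d1 (0.28) and Cry2 (0.16) rose in females, while Nr1d2 fell in males (-0.30). Over both sexes, again in lists not called there, the immediate early gene Jun (0.22), the microglial receptor gene Trem2 (0.18) and the matrix gene Bcan (0.15) rose, and Gphn (-0.12), Gria4 (-0.13), Pde10a (-0.14), Pclo (-0.17), Hspa4l (-0.19) and Dnajc3 (-0.15) fell.

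Some lists gave no call in any of the 4 housing comparisons by camera. These were blood cells, ependymal cells, habenula, hippocampus, hypothalamus, striatum, thalamic reticular neurons, thalamic ion channels, synaptic vesicle machinery, monoamine and acetylcholine receptors, stress-hormone and neuropeptide receptors, neurotrophins, perineuronal net genes, imprinted genes and mitochondrially encoded genes. Glucocorticoid-responsive genes gave none either (adjusted p = 0.923 over both sexes). Fry did call neurotrophins over both sexes (adjusted p = 0.0256) and in females (0.0131). The imprinted list was tested on 24 genes, without noncoding members such as H19, Meg3, Kcnq1ot1 and Airn, which did not match.

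The sexes differed in myelin genes among control offspring. Males minus females, the median log2 fold change of the 23 genes was -0.43 in control offspring, where 19 were lower in males, and 0.018 in SIR offspring. Over all genes, males and females differed in 1103 genes in control offspring (3505 at an unadjusted p under 0.05) and in 498 in SIR offspring (2788). The library labelled SIR female 5, with its male-like sex-linked transcripts, is among the SIR females, and without it 564 genes differed in SIR offspring (2876), with a myelin median of 0.024. The mean myelin score was 0.21 ± 0.08 (SD, n = 8) in control females, -0.20 ± 0.16 (n = 8) in control males, -0.01 ± 0.13 (n = 8) in SIR females and 0.00 ± 0.12 (n = 7) in SIR males. All 23 list members were expressed at 1 CPM or more and none was in another list. One hypothesis is that the amount of white matter in the tissue differed between control males and females and could bring the interaction, but the median stayed at 0.416 with 3 region components, which hold none of the 23 genes and so leave this open.

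Region markers varied widely between libraries of 1 group. Ttr, the main transcript of choroid plexus, was at 1564.23 CPM in control female 20, with group levels of 233 ± 539 CPM (SD, n = 8) in control females, 9.62 ± 13.1 (n = 8) in control males, 43.3 ± 77.8 (n = 8) in SIR females and 1.73 ± 1.30 (n = 7) in SIR males. The hypothalamic neuropeptide gene Hcrt ranged from 0.23 to 61.44 CPM in SIR females and from 0.73 to 112.62 CPM in control females. Slc6a3 stood at 8.21 CPM in control females and 0.351 CPM in SIR females. Of the midbrain list 9 of 14 genes were measured, 5 at 1 CPM or more and 1 held by another list, and of the choroid plexus list 16 of 18, 11 of them at 1 CPM or more. A candidate source of these transcripts is tissue of neighbouring regions taken with the thalamus, as a hypothesis, and the count of 480 genes called in females with 3 region components, against 688 without them, neither excludes nor shows it.

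Libraries of 1 group with numbers at most 3 apart were tested for resemblance, as littermates or animals handled together might show it. The mean correlation of residuals was -0.116 over 11 such pairs and -0.143 over all pairs of 1 group, at percentile 76.4 of 100000 random renumberings (permutation p = 0.236, 1-sided). No resemblance was detected with these few pairs, and this leaves differences between the number ranges of the housing groups untested.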
